A study of Arabidopsis thaliana with 4 samples.

How the data were processed

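RNA was measured in dissected shoot apices of 10-day-old Arabidopsis plants of 2 genotypes, Col-0 wild type and nse4a-2, each in control medium and after 24 h in 20 µM zebularine. The labels describe poly(A) RNA read as single ends, and the strand kept by the library is not stated. The series lists 1 sample per group, but per the file headers the deposited table holds biological replicates R1 and R2 of each of the 4 groups, which makes 8 libraries. The raw read count per gene and replicate was made by the authors, per the file headers without normalization, from reads aligned to TAIR10. The submitters' processing notes name TopHat2 and Cuffdiff without versions or roles, and the counting tool, annotation and filters are not stated. The FPKM values of each replicate, with their mean and SD per group, were computed by the authors, as deposited. The adjusted p value, log2 fold change and yes or no call of 3 comparisons were computed by the authors, per the file headers at an adjusted p below 0.05, and are rounded to 3 decimals. The authors' table holds no call for nse4a-2 against wild type in zebularine.

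The table lists 32399 genes, of which 43 have no values and 8190 have 0 counts in every library. Gene names came from the table and from a TAIR10.1 annotation in which 31892 of its genes were found by locus tag, and no coordinates are given since the builds differ by name. Of the deposited columns, 12 per-sample columns (FPKM of single replicates and their SD) were not used here. The groups, comparisons, gene lists, naming rule, size rule and first alternatives were fixed before the data were examined. That plan assumed 1 library per group and FPKM, and gave edgeR's quasi-likelihood test as its fallback for replicated counts, which applied. Raw counts were filtered with filterByExpr, which left 19682 genes, scaled by TMM and fitted in 1 model of the 4 groups with edgeR 4.0.16 under R 4.3.3 (limma 3.58.1). The 5 contrasts were zebularine against control in each genotype, nse4a-2 against wild type in each medium, and the difference of both zebularine responses. A gene was called at a 2-sided adjusted p below 0.05 from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested. The SE of a log2 fold change is its size divided by the square root of the F statistic. The common biological coefficient of variation was 13.4%. Deviations of same-numbered replicates correlated between groups at r of −0.086 to 0.234 across genes, and replicate 2 scored above replicate 1 on principal component 1 in each of the 4 groups. The headers do not say that replicates were paired across groups, so their number was not a term of the model, and a fit with it as a block is among the alternatives. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

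Total counts per library ran from 15360494 to 19811948, where 3 counts correspond to 0.151 to 0.195 CPM. A value of 3 is the upper limit at 95% confidence on the expected count where 0 was counted. The 10 most abundant genes took 3.39 to 4.08% of the counts of a library, and TMM factors ran from 0.957 to 1.03. A fold against a group with 0 counts is given as a lower bound against a floor of 3 counts over the group's 2 libraries. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. Genes with near-identical copies, such as the H3.1 and H4 histone genes and the ribosomal S5 genes, are reported as uncertain. The procedure was tested on simulated data with the real library sizes and few changed genes, all in 1 group. Each gene had the spread fitted for its expression level, without gene-specific spread or a shift between replicates. The shares below therefore need not hold for the real data. In that test the procedure recovered 67.7, 75.0, 69.7, 77.1 and 42.7% of 2-fold changes in the 5 contrasts in the order above, and 92.9, 97.0, 92.9, 98.0 and 93.9% of 4-fold ones. False calls were 6 of 165, 14 of 182, 7 of 168, 6 of 177 and 11 of 145, so that the share passed 5% for zebularine in nse4a-2 and for the difference.

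The size rule called a gene at a 2-fold change or more of (FPKM + 1) between group means, at a mean FPKM of at least 1, which 18583 genes reached. It gave 481 genes higher and 129 lower for zebularine in wild type, 836 and 173 in nse4a-2, 493 and 165 for the genotype in control medium, 1105 and 300 in zebularine, and 623 and 325 for the difference. Genes were named by a rule: NSE4A and the other SMC5/6 subunits, per comparison the 8 largest rises and 8 largest falls of log2(FPKM + 1) among genes the authors call (or past the size rule where they give no call), up to 4 members of each list with the largest change, and for the difference the 5 largest each way. Other genes are marked as chosen after values were seen, or are called members of a list. The 22 lists were SMC5/6 complex, cohesin and condensin, DNA damage inducible, damage sensing and repair, G2/M, S phase, histone H3.1 and H4, DNA methylation and silencing, methylation-silenced reporters, shoot meristem and flowering, salicylic acid and defence, jasmonate and wounding, heat and unfolded protein, oxidative and xenobiotic, low oxygen, circadian clock, pyrimidine metabolism, housekeeping, markers of leaf photosynthesis, root and stomatal lineage, and transposable element genes. Each list's calls are also given adjusted over the list alone. The list's median log2 fold change is set beside the central 95% of 10000 random lists matched on expression in 20 bins, for 110 medians in all. Random lists were drawn from genes of the same libraries, so their range shows spread across genes and not between replicates. Genes that vary together between replicates can leave that range without a difference between groups. Alternatives were each library left out in turn, RLE scaling, no low-count filter, a replicate block, a fit of the 2 groups alone, DESeq2 1.42.0, a stricter adjusted p, and other pseudocounts, minimum FPKM and fold sizes for the size rule. Leaving out each library was planned for counts of changed genes, in case the table held several libraries per group. Leaving libraries out for list medians, named genes and shared genes, and the other edgeR and DESeq2 alternatives, were chosen after seeing the data.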

Results

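Poly(A) RNA was sequenced from dissected shoot apices of Arabidopsis thaliana, ecotype Col-0. The plants were wild type or carried nse4a-2, a mutant allele of NSE4A (AT1G51130), whose product is the kleisin subunit of the SMC5/6 complex, a chromosome-structure ATPase that acts in DNA repair. Seedlings aged 9 days went into liquid medium with or without 20 µM zebularine, a cytidine analogue that enters DNA and traps DNA methyltransferases on it, and apices were taken 24 h later. The 4 groups, WT_ctrl, nse4a-2_ctrl, WT_zeb and nse4a-2_zeb, held 2 biological replicates each. Total read counts were 18102518 and 15420525 in WT_ctrl, 15360494 and 16208143 in nse4a-2_ctrl, 19811948 and 19104013 in WT_zeb, and 16172625 and 17297457 in nse4a-2_zeb. Between 21682 and 22169 genes had reads in a library. The replicates of a group correlated across genes at r of 0.986 in WT_ctrl, 0.980 in nse4a-2_ctrl, 0.981 in WT_zeb and 0.986 in nse4a-2_zeb, and genes are not independent replicates. Principal component 1 carried 57.2% of the variance, and the nse4a-2_zeb libraries scored 70.5 and 86.5 on it, apart from the 6 others at −63.4 to 5.30. Values below are means of library-scaled read counts (CPM) ± SD of n = 2 libraries, and log2 fold changes ± SE.

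NSE4A itself was read in every group. It stood at 9.89 ± 1.03 CPM in WT_ctrl, 8.14 ± 0.401 in nse4a-2_ctrl, 11.7 ± 1.55 in WT_zeb and 19.82 ± 1.79 in nse4a-2_zeb. NSE4A rose in the mutant with zebularine by 1.29 ± 0.17 log2 (adjusted p 0.00156). Its change in wild type, 0.23 ± 0.17, did not pass (adjusted p 0.590), and neither did the difference between both responses, 1.06 ± 0.24 (adjusted p 0.0771). In control medium the mutant differed from wild type by −0.30 ± 0.17 (adjusted p 0.407), and in zebularine NSE4A was higher in the mutant by 0.76 ± 0.16 (adjusted p 0.00999). That last call was lost without WT_zeb replicate 1 or without nse4a-2_zeb replicate 2, over a range of 0.62 to 0.92 when each library was left out. The labels do not give the lesion of nse4a-2, so a gene-level count does not check the genotype. NSE4B, the paralogous kleisin, had 0 reads in all 8 libraries, which at 95% confidence allows at most 0.195 CPM in a library. Of the 9 SMC5/6 genes tested, NSE4A was the only call in the mutant with zebularine and between genotypes in zebularine, over all genes and adjusted over the list alone. In wild type with zebularine the ATPase subunit SMC5 changed by 0.31, NSE3 by −0.60 and the loading factor ASAP1 by 0.34, none past the test. In the mutant, SMC5 changed by 0.05, SMC6A by −0.26 and SMC6B by 0.07, also not past it.

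**Figure D1:**
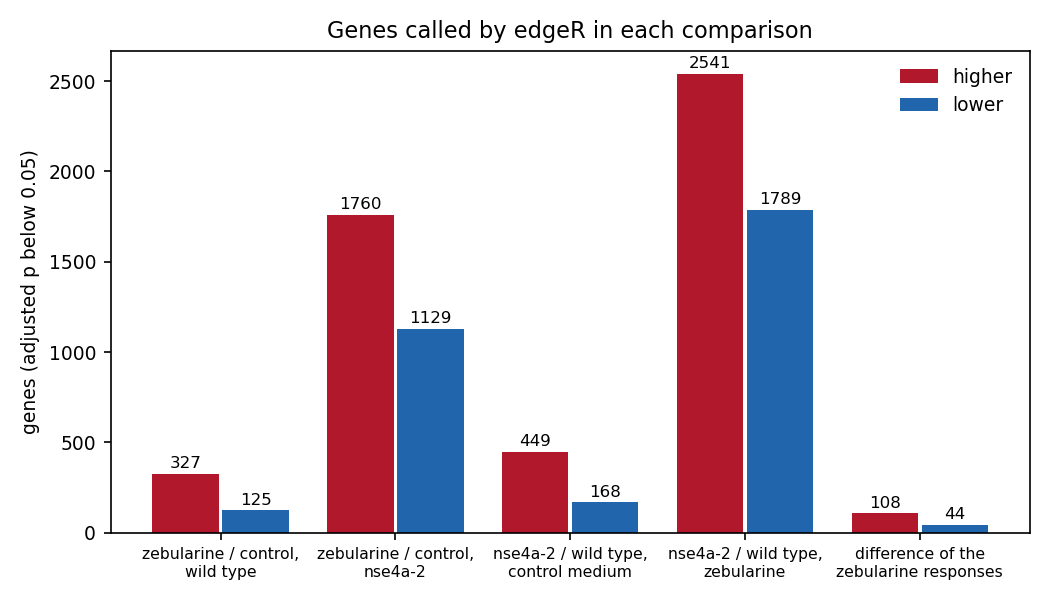
Bars give the number of genes that edgeR called higher (red) and lower (blue) at an adjusted p below 0.05 in each of the 5 contrasts. The genotype contrast in zebularine holds the most calls, 2541 higher and 1789 lower, and the difference of responses the fewest, 108 and 44.

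In wild type after 24 h of zebularine, genes of the DNA damage response and morning genes of the circadian clock were higher, and evening clock genes were lower. For the clock genes an effect of zebularine cannot be told apart from another harvest hour, since harvest hours are not given. Genes of G2 and mitosis ran lower as a group. The comparison asks how apices with an intact SMC5/6 complex answer zebularine. Of 19682 genes tested, 327 rose and 125 fell. GMI1 (AT5G24280), a hinge-domain protein induced by gamma irradiation, went from 11.7 ± 3.11 to 36.2 ± 0.763 CPM, a rise of 1.63 ± 0.18 (adjusted p 0.00407). NAC044 (AT3G01600), a transcription factor related to the damage regulator SOG1, rose by 2.25 ± 0.19 (adjusted p 0.00147), from 3.61 ± 0.0728 to 17.3 ± 0.0149 CPM. SMR7 (AT3G27630), an inhibitor of cyclin-dependent kinases, rose by 2.67 ± 0.35 (adjusted p 0.00840), from 18 to 134 reads. Its relative in the pathway NAC085 (AT5G14490) went from 3 to 39 reads (adjusted p 0.0214). BRCA1, a repair ubiquitin ligase, rose by 0.96 and the poly(ADP-ribose) polymerase PARP2 by 0.87. These were the 6 risers among 22 damage-inducible genes tested, and 10 rose and 1 fell when adjusted over the list alone. The list's median was 0.325, against −0.114 to 0.094 for 95% of random lists. Among 19 genes of damage sensing and repair, RAD17, which loads the checkpoint clamp, was the only call, over all genes and adjusted over the list alone, at 0.78 ± 0.15 (adjusted p 0.0354). The clamp subunit HUS1 at −0.42, the mismatch-repair protein MSH6 at −0.35 and the nuclease FAN1 at −0.40 did not pass.

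The smallest adjusted p in wild type was shared by the clock genes CCA1 and LHY and by RCI2A. CCA1 (AT2G46830) rose by 2.49 ± 0.14 and LHY (AT1G01060) by 2.76 ± 0.17, each at adjusted p 0.000194. These MYB repressors peak at dawn, as does the MYB activator RVE8, which rose by 2.11. The evening-complex genes ELF4 and ELF3 fell by 3.02 ± 0.47 (adjusted p 0.0148) and 0.59, and the evening repressor TOC1 fell by 0.97. PRR9, a day-phase repressor, stood at 2.54 ± 0.58 without passing (adjusted p 0.0565). Adjusted over the list alone, 4 clock genes rose and 5 fell of 11 tested, and the list's median was −0.051, with members going both ways. The clock-controlled RNA-binding protein GRP7 fell by 2.27 ± 0.34 (adjusted p 0.0132), from 3770 ± 287 to 784 ± 434 CPM. JMJD5, a histone demethylase of the evening, fell by 2.87 ± 0.31, the pseudo-response regulator PRR3 by 2.85 ± 0.25, the CCT-motif gene AT1G07050 by 3.07 ± 0.50 and AT4G32340 by 2.74 ± 0.43. COR27, a cold-regulated evening gene, stood at −2.68 (adjusted p 0.139). AT2G36040, from 6 reads to 0, was under the low-count filter.

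Mitotic genes moved down together in wild type, and 3 were called singly. CDC20.1, an activator of the anaphase-promoting complex, fell by 0.76 ± 0.15 (adjusted p 0.0385), and the Aurora kinases AUR2 and AUR1 fell by 0.66 ± 0.12 and 0.64. Those were the 3 calls of 22 G2/M genes, 16 fell when adjusted over the list alone, and the median was −0.58, against −0.109 to 0.09 in random lists. Beside it, the leaf photosynthesis markers had a median of 0.226 (random lists −0.105 to 0.155) and the stomatal markers −0.409 (−0.267 to 0.335). The B-type cyclin CYCB2;2 at −0.67 and CDC20.2 at −0.70 did not pass, and CDC20.2 is a near-identical neighbour of CDC20.1, so that their reads are uncertain. Of 22 S-phase genes, the licensing factor CDT1A fell by 0.62 ± 0.13 (adjusted p 0.0415), and 9 fell when adjusted over the list alone. The list median was −0.312, with CDC6 at −0.53, CDC45 at −0.53 and CYCA3;1 at −0.65 not past the test.

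Stress genes also moved in wild type. The jasmonate list had a median of 1.42, and LOX3, a lipoxygenase of jasmonate synthesis, rose by 2.80 ± 0.53 (adjusted p 0.0303), while the defensin PDF1.2 fell by 2.22. Adjusted over the list alone, 9 of 14 jasmonate genes rose and 1 fell. The jasmonate repressors JAZ5 and JAZ8 stood at 2.58 and 2.81 without passing, and TAT3 went from 4 to 31 reads (adjusted p 0.171). Of 9 oxidative and xenobiotic genes, the glutathione transferase GSTU24 rose by 1.85 ± 0.28, the auxin glucosyltransferase UGT74E2 by 2.35 ± 0.51 (adjusted p 0.0495) and the catalase CAT2 by 1.19, and 7 rose adjusted over the list alone. The zinc-finger gene ZAT12 at 1.496 and GSTU25 at 1.33 did not pass. ADH1, alcohol dehydrogenase, rose by 1.34 ± 0.17 and was the only call of 9 low-oxygen genes, of which 2 rose adjusted over the list alone. The low-oxygen genes LBD41 at −0.95, HRA1 at −1.14 and PCO2 at −1.14 did not pass. LHCB2.1, a light-harvesting gene with a close copy, rose by 1.40 ± 0.16, alone among 10 leaf photosynthesis markers, and 2 of them rose adjusted over the list alone. LHCA1 at 0.74, GAPA at 0.31 and RCA at 0.64 did not pass. The B-box gene BBX29 rose by 3.24 ± 0.59, the calmodulin-like CML37 by 3.27 ± 0.65, the copper protein BCB by 2.66 ± 0.57 and the AP2-domain gene AT1G33760 by 2.90 ± 0.57. WRKY40, a defence regulator, stood at 2.60 (adjusted p 0.0604).

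The ribosomal S5 gene AT1G58684 and LpxC2 went from 0 reads to 977 and 232, at least 283-fold and 65.7-fold higher, with adjusted p of 0.136 and 0.144, and both have near-identical copies, so that their counts are uncertain. Transposable element genes gave 1 rise and 1 fall of 94 tested, AT3G28160 at 1.05 and AT4G16870 at −1.24, over all genes and adjusted over the list alone. Of 2316 transposable element genes with values 94 passed the low-count filter, and of 10 methylation-silenced reporters 3 did. Results for these lists do not cover the members under the filter. edgeR called 0 genes of several other lists, and the number at an unadjusted p below 0.05 and the number called by DESeq2 are given here. They were 1 and 0 of 9 SMC5/6 genes, 0 and 0 of 13 cohesin and condensin genes, 2 and 0 of 13 histone H3.1 and H4 genes, and 1 and 1 of 23 methylation and silencing genes. They were 0 and 0 of 3 methylation-silenced reporters, 3 and 1 of 19 meristem and flowering genes, 9 and 0 of 19 salicylic acid genes and 4 and 0 of 8 heat genes. For pyrimidine metabolism they were 2 and 0 of 9, for housekeeping genes 2 and 1 of 9, for root markers 2 and 0 of 6, and for stomatal markers 3 and 0 of 7. Adjusted over the list alone, 1 meristem gene and 3 heat genes rose, 1 heat gene fell, and the other 10 of these lists had 0. The salicylic acid list had a median of 0.689 (random lists −0.153 to 0.129), and its 9 genes at an unadjusted p below 0.05 were all higher. The heat list had a median of 0.708 (random lists −0.378 to 0.484). The methyltransferase gene DRM1 stood at 2.53 (adjusted p 0.0954), the reporter SDC at 1.33, QQS at 0.42 and BNS at 0.23. The meristem gene KNAT6 stood at 0.70 (adjusted p 0.0565), the defence genes CBP60G at 1.71, WRKY38 at 1.56 and PR1 at −1.33, and PR2 went from 2 to 8 reads. Of the heat genes, HSP17.4 went from 0 to 26 reads, at least 7.43-fold higher (adjusted p 0.0713), BIP3 from 3 to 28 reads, and HSFA2 changed by −1.64. Thymidine kinase TK1A at 0.55, the actin ACT2 at 0.18, the root genes COBL9 at −1.84 and PRP3 at −2.92, and the stomatal regulators MUTE at −0.77 and FAMA at −0.41 did not pass.

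The wild-type counts rested on single libraries. Without WT_ctrl replicate 1, 18 genes rose and 5 fell, with 6 of 25 rule-named calls passing. Of the list counts above only the damage rises, 2, and the clock rises, 3, were then above 0, and the G2/M, jasmonate, oxidative and other counts went to 0. With DESeq2 and the replicate block the G2/M falls numbered 8 and 5, the jasmonate rises 4 and 5, the oxidative rises 4 and 5, the low-oxygen rises 2 and 2, the leaf marker rises 3 and 1, and the transposable element falls 2 and 2. CCA1, LHY, RVE8, GMI1, NAC044, JMJD5 and PRR3 were called without any 1 of the 8 libraries. Without WT_ctrl replicate 2 there were 447 and 79, without WT_zeb replicate 1 there were 189 and 65, and without WT_zeb replicate 2 there were 159 and 124. In each such fit the lone sample left is assumed to vary like the other groups.

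In nse4a-2, zebularine changed more genes than in wild type, by a margin that depended on the rule and the libraries, and the response was one of DNA damage, salicylic acid defence and oxidative stress, with lower mitotic and histone genes. The comparison asks how apices with the mutant SMC5/6 subunit answer the same dose. Of 19682 genes, 1760 rose and 1129 fell. The size rule gave 836 and 173 here against 481 and 129 in wild type, and without nse4a-2_zeb replicate 2 edgeR gave 552 and 161 against 336 and 101. Among the damage-inducible genes 15 of 22 rose and 1 fell, with a median of 0.809 (random lists −0.174 to 0.16), and 17 rose and 2 fell adjusted over the list alone. GMI1 went from 56.0 ± 7.68 to 197 ± 8.62 CPM, a rise of 1.82 ± 0.17 (adjusted p 0.000309). SMR7 rose by 2.57 ± 0.24 (adjusted p 0.000329), NAC044 by 1.77 ± 0.17 and NAC085 by 2.69 ± 0.25. BRCA1 rose by 1.18, the chromatin remodeller RAD54 by 0.57, PARP1 by 0.63, PARP2 by 1.26, the meiotic and repair gene XRI1 by 1.74, the cohesin SYN2 by 0.83, the replication protein RPA1E by 0.79 and the mitotic cyclin CYCB1;1 by 0.56. BARD1, the partner of BRCA1, fell by 0.59. RAD17 rose by 0.90 ± 0.15 (adjusted p 0.00408) as the only call of 19 sensing and repair genes, over all genes and adjusted over the list alone, with RAD9 at −0.57, LIG4 at 0.38 and MSH6 at −0.37 not past it. The kleisin SYN3 fell by 0.89 ± 0.16 and the condensin subunit CAP-D3 by 0.51 ± 0.14, the 2 calls of 13 cohesin and condensin genes either way of adjusting. CAP-D2 at −0.41 and CAP-H at −0.38 did not pass.

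Salicylic acid genes rose widely in the mutant, 16 of 19, and 18 adjusted over the list alone, with a median of 2.19 against −0.201 to 0.228 in random lists. PBS3 (AT5G13320), which conjugates isochorismate on the way to salicylic acid, rose by 4.998 ± 0.34 (adjusted p 0.000112), from 0.947 ± 0.194 to 30.3 ± 10.3 CPM. The isochorismate exporter EDS5 rose by 3.08 ± 0.25 (adjusted p 0.000195), the synthase ICS1 by 1.88, the N-hydroxypipecolate enzyme FMO1 by 4.04 ± 0.50 and the camalexin enzyme PAD3 by 3.58 ± 0.41. The lipase-like regulators EDS1, PAD4 and SAG101 rose by 2.19, 3.06 and 1.88. The transcription factors SARD1 and CBP60G rose by 2.21 and 2.64, the salicylic acid receptor NPR1 by 0.89, PR2 by 2.81 and PR5 by 0.83. PNP-A, a small natriuretic-type peptide, rose by 6.58 ± 0.29 (adjusted p 1.25e-05), the kinase ARCK1 by 5.30 ± 0.41, the phosphoglycerate mutase-like AT3G60420 by 5.09 ± 0.26 and the EF-hand gene AT3G47480 by 4.98 ± 0.34. Also among the 8 highest were the late-embryogenesis gene AT3G53040 at 4.83 ± 0.21, AT3G57460 at 5.75 ± 0.54, AT5G44585 at 4.21 ± 0.35 and the SKP1-like SK9 at 4.45 ± 0.40. TAT3, a tyrosine aminotransferase, had 1 read in the mutant control and 695 in zebularine (adjusted p 0.000221), the only call of 14 jasmonate genes over all genes and adjusted over the list alone. JAZ1 at 0.48, JAZ7 at −0.91 and VSP2 at 1.16 did not pass. The cold-regulated genes LTI78 and LTI30, named by the rule between genotypes, rose by 2.34 ± 0.41 and 3.70 ± 0.35 here.

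All 13 histone H3.1 and H4 genes fell in the mutant with zebularine, over all genes and adjusted over the list alone, with a median of −0.961 against −0.215 to 0.159 in random lists. The copies are near-identical, so single values are uncertain, and their summed CPM went from 1784 to 947. H3.1 gene AT3G27360 fell by 1.28 ± 0.17, and the H4 genes AT3G45930, AT3G46320 and AT5G59970 by 1.11, 1.13 and 1.05. Of 22 G2/M genes 14 fell, 19 adjusted over the list alone, with a median of −0.666, beside medians of 0.422 for the leaf markers (random lists −0.266 to 0.164) and −0.563 for the stomatal ones (−0.367 to 0.452). They included the cyclins CYCB1;2 at −0.88 ± 0.18 and CYCB1;3 at −0.80 ± 0.16, CDC20.1 at −0.84 ± 0.15, the spindle protein PLE at −0.80 ± 0.17, the cytokinesis syntaxin KN at −0.76 and TPX2 at −0.77. In S phase 5 genes fell and 1 rose of 22, and 7 and 1 adjusted over the list alone. The helicase subunit MCM7 fell by 0.62 ± 0.11, the sliding clamps PCNA1 and PCNA2 by 0.53 and 0.58, and MCM4 and MCM5 by 0.48 and 0.41, while the polymerase epsilon subunit TIL1 rose by 0.91 ± 0.20. Of 23 methylation and silencing genes, the chromomethylase CMT3 fell by 0.64 ± 0.12 and AGO4 by 0.55 ± 0.11, and DRM1 rose by 2.96 ± 0.46 and MORC6 by 0.45, with NRPE1 at −0.51 not past it. The list alone gave the same 2 and 2. None of the 3 methylation-silenced reporters tested, of 10 listed, was called. Here edgeR and DESeq2 called 0, adjusted over the list alone 0, and 1 had an unadjusted p below 0.05. SDC stood at −0.37, QQS at 0.00 and BNS at −0.40.

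Among oxidative and xenobiotic genes 7 of 9 rose, 8 adjusted over the list alone, with a median of 1.56. The mitochondrial alternative oxidase AOX1A rose by 2.09 ± 0.24, GSTU24 by 2.92 ± 0.23, GSTU25 by 2.31 ± 0.36, UGT74E2 by 2.43 ± 0.38 and NAC013 by 1.56. The chaperones HSP90.1 and HSP70 rose by 1.58 and 1.26, the heat factor HSFA2 by 2.38 and BIP3 by 1.72, the 4 calls of 8 heat genes either way of adjusting. ADH1 rose by 2.19 ± 0.16 and the sucrose synthase SUS1 by 2.099 ± 0.14 (adjusted p 8.96e-05), while the cysteine oxidases PCO2 and PCO1, which are induced in low oxygen, fell by 2.61 and 1.46. Adjusted over the list alone, 2 low-oxygen genes rose and 4 fell of 9, and HRA1 at −1.80 did not pass over all genes. Of 11 clock genes 6 rose, either way of adjusting, with a median of 1.19: LHY by 2.41 ± 0.17, CCA1 by 1.62 ± 0.13, RVE8 by 1.83 ± 0.25, PRR9 by 2.94 ± 0.51, PRR7 by 1.19 and GI by 1.29. In the meristem list the homeobox gene KNAT6 rose by 0.74 ± 0.15 and the floral integrator SOC1 by 0.94 ± 0.18, and ANT and AS1 fell by 0.53 and 0.62, either way of adjusting, of 19 tested. FUL at 0.85 and CUC3 at −1.26 did not pass. TK1A rose by 0.86 and the uracil catabolism genes PYD1 and PYD3 by 0.58 and 0.59, of 9 pyrimidine genes, and 1 more fell adjusted over the list alone, where CDA1 stood at −0.50. UBC9 rose by 0.49 as the only call of 9 housekeeping genes either way of adjusting, beside UBQ10 at 0.46, GAPC2 at 0.25 and ACT2 at 0.13.

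Of 10 leaf photosynthesis markers, LHCB2.1 rose by 2.24 ± 0.17, LHCA1 by 1.28 ± 0.19 and RCA by 0.78 ± 0.22, either way of adjusting. COBL9, a root-hair gene, rose from 6 to 99 reads, the only call of 6 root markers either way, with PRP3 at −2.64, MYB36 at 0.66 and CASP1 at −0.85. The stomatal peptide EPF2 fell by 1.82 ± 0.23 and the receptor TMM by 1.10 ± 0.30, of 7 stomatal markers, and 4 fell adjusted over the list alone, with SPCH at −0.56 and MUTE at −1.03. HY5, the light-signalling bZIP factor, fell (adjusted p 0.000265), as did the GATA factor CGA1 by 2.01 ± 0.22 and BGLU22, a glucosidase with a close copy, by 4.34 ± 1.21. The jacalin-type lectins AT2G25980 and AT1G52070 went from 122 and 106 reads to 0, at least 42.7-fold and 37.4-fold lower. AT4G10270 at −2.096 did not pass, and the ribosomal gene AT1G59359, uncertain for its near-identical copies, went from 111 reads to 0 without passing (adjusted p 0.263). Those 111 reads came from a single library of nse4a-2_ctrl (3.46 ± 4.89 CPM). Of 94 transposable element genes 3 rose and 2 fell, and 2 and 1 adjusted over the list alone.

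Counts in the mutant fell without single libraries, nse4a-2_zeb replicate 2 above all. Without that library 552 genes rose and 161 fell, the G2/M list gave 1 fall, and 41 of 68 rule-named calls passed. The falls of the S-phase, silencing, meristem, and cohesin and condensin lists then went to 0, as did the RAD17 rise. Without nse4a-2_ctrl replicate 1 there were 812 and 559, 51 of 68 named calls, 10 salicylic acid, 11 damage, 2 heat and 0 pyrimidine rises, 0 meristem, S-phase and transposable element rises, 1 silencing rise and 0 low-oxygen falls. Without nse4a-2_ctrl replicate 2 the BARD1 and transposable element falls and the UBC9 rise were not called, and without nse4a-2_zeb replicate 1 there were 1292 and 581. The histone list gave 11 to 13 falls over the 8 fits.

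The authors' own calls, from the same libraries, gave 843 genes higher and 279 lower in wild type and 1665 and 735 in nse4a-2. Of the edgeR calls, 398 of 452 in wild type and 2002 of 2889 in the mutant were also theirs, in the same direction. By the authors' calls the 2 genotypes shared 410 higher and 92 lower genes, against 43.4 and 6.3 for independent lists over 32356 genes. That base includes 8190 genes with 0 counts in every library, which makes the expected numbers too low. By edgeR the genotypes shared 156 higher, among them GMI1, SMR7, NAC044, NAC085, LHY and CCA1, and 51 lower, against 29.2 and 7.2 over the 19682 genes tested. Without 1 library the shared higher genes numbered between 15 and 210 and the lower ones between 1 and 37, and the lowest counts, 15 and 1, came without WT_ctrl replicate 1. The shared higher genes numbered 95 without WT_zeb replicate 2 and 97 without nse4a-2_zeb replicate 2. The shared lower genes numbered 28 without WT_ctrl replicate 2, 31 without nse4a-2_ctrl replicate 1, 17 and 31 without WT_zeb replicate 1 or 2, and 14 without nse4a-2_zeb replicate 2.

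**Figure D2:**
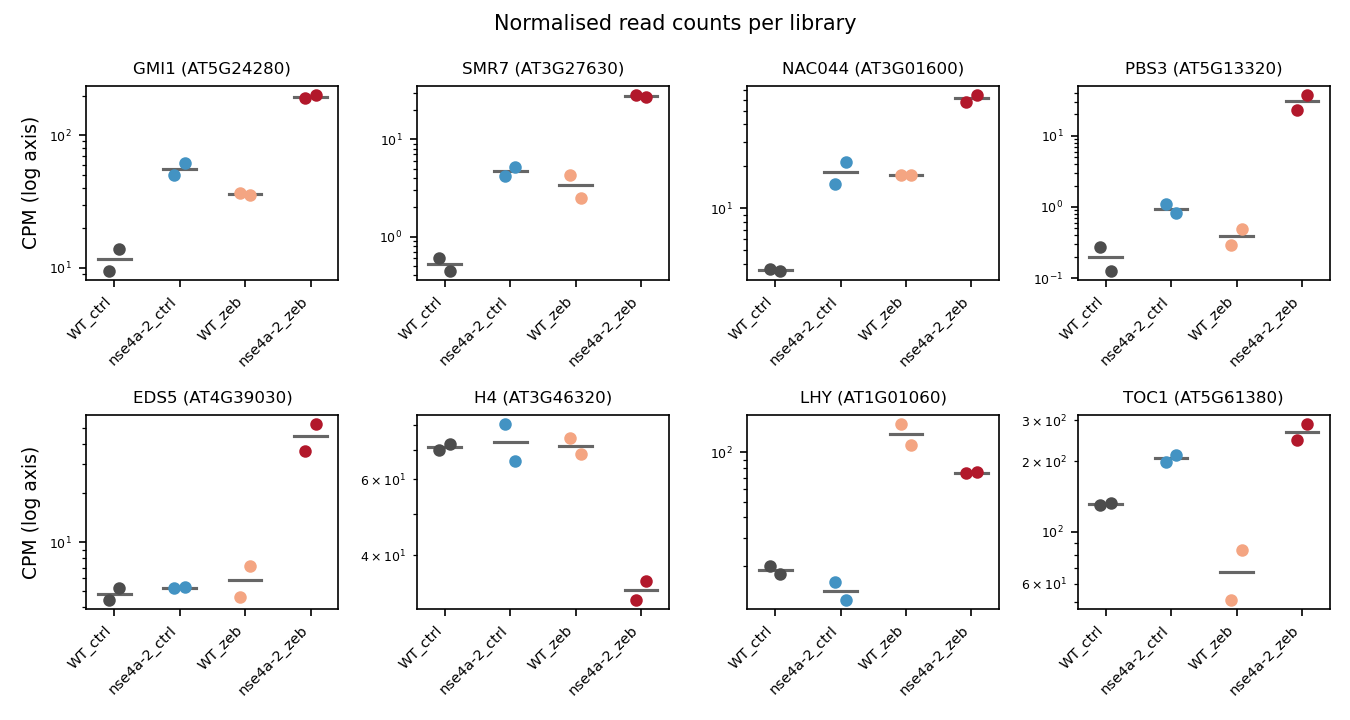
CPM of GMI1, SMR7, NAC044, PBS3, EDS5, the H4 gene AT3G46320, LHY and TOC1 on logarithmic axes that differ between panels, with 1 point per library and a line at each group mean. GMI1 runs from a mean of 11.7 in WT_ctrl to 197 in nse4a-2_zeb, and PBS3 reaches 30.3 in nse4a-2_zeb.

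In control medium the mutant already carried a raised damage response, together with higher LTI78, COR15A, COR15B, LTI30 and KIN1 and a few genes whose reads were nearly or wholly missing. The comparison asks how the nse4a-2 line differs from wild type without the drug. With a single mutant line, an effect of the lesion cannot be told apart from other differences between the lines. Of 19682 genes 449 were higher and 168 lower in nse4a-2. GMI1 was higher by 2.25 ± 0.18 (adjusted p 0.000691), NAC044 by 2.30 ± 0.19 (adjusted p 0.000828) and SMR7 by 3.13 ± 0.35 (adjusted p 0.00314), and NAC085 went from 3 to 101 reads (adjusted p 0.00156). With PARP2 at 1.12, the ribonucleotide reductase subunit TSO2 at 0.53 and GR1 at 0.71 they were the 7 calls of 22 damage-inducible genes, and 12 adjusted over the list alone. The list median was 0.49 against −0.13 to 0.108. RAD17 was higher by 1.18 ± 0.15, alone of 19 sensing and repair genes either way of adjusting, with ATM at −0.26, XRCC1 at −0.27 and MSH6 at −0.27.

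LTI78, COR15A, COR15B, LTI30 and KIN1, known from the cold response, were among the 8 largest rises by the naming rule. The cold and drought marker LTI78 (AT5G52310) went from 30.7 ± 3.85 CPM in WT_ctrl to 377 ± 95.2 in nse4a-2_ctrl, higher by 3.60 ± 0.44 (adjusted p 0.00441). COR15A, a chloroplast protectant, was higher by 3.60 ± 0.39, its neighbour COR15B by 3.16 ± 0.37, LTI30 by 3.71 ± 0.46 and KIN1 by 3.45 ± 0.27. The RING-finger gene AT5G60250 was higher by 4.09 ± 0.27 (adjusted p 0.000342). AT1G58684, uncertain as above, had 245 reads against 0, at least 85.3-fold higher, without passing (adjusted p 0.248). All of those reads came from a single library of nse4a-2_ctrl (7.64 ± 10.8 CPM), so the bound rests on that library. AT3G28320 had 0 reads in nse4a-2_ctrl against 364, at least 114-fold lower, and the cyclin-family gene AT1G20590 had 0 against 64, at least 20.3-fold lower. AT3G01345 was lower by 7.43 ± 0.75, with 6 reads against 1112, and the thioredoxin ACHT5 by 2.82 ± 0.58. The phosphoethanolamine methyltransferase gene XPL1 at −3.29 and AT2G20670 at −2.92 did not pass, and AT5G40855, with 0 against 10 reads, was under the low-count filter.

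Smaller calls in control medium fell in several lists. PR1, a salicylic acid marker, was higher by 2.60 ± 0.54 (adjusted p 0.0330), the only call of 19 in its list, of which 5 were higher adjusted over the list alone, with PAD4 at 1.35 and PBS3 at 2.15 not past it and PR2 at 2 reads in wild type and 20 in the mutant. The salicylic acid list had a median of 0.585 (random lists −0.161 to 0.164). GSTU24, the mitochondrial stress gene UPOX and NAC013 were higher by 1.41, 1.06 and 0.79, the 3 calls of 9 oxidative genes, where 6 were higher and 1 lower adjusted over the list alone. The oxidative list had a median of 0.997 (random lists −0.226 to 0.248). ADH1 was higher by 1.995 ± 0.17 and SUS1 by 1.53 ± 0.15, and the low-oxygen factor LBD41 was lower by 3.12 ± 0.63, with HRA1 at −2.28 not past it, and 4 of 9 were higher and 4 lower adjusted over the list alone. CCA1 was higher by 0.64, alone of 11 clock genes, where 3 and 3 passed adjusted over the list alone, and ELF4 at 1.57, PRR5 at 1.26 and RVE8 at −0.73 did not pass. KNAT6 was higher by 0.83 ± 0.16, alone of 19 meristem genes, and 3 adjusted over the list alone, with CUC1 at 1.13. HSP70 was lower by 0.91, alone of 8 heat genes, where 3 were higher and 2 lower adjusted over the list alone. The H4 gene AT1G07660 was lower by 1.59 ± 0.17 and AT3G53730 higher by 0.60 ± 0.13, uncertain for their near-identical copies, and of 13 histone genes 2 were higher and 1 lower adjusted over the list alone. LHCB2.1 was lower by 1.01 ± 0.16 and the polyubiquitin UBQ10 higher by 0.93 ± 0.21, each alone in its list of 10 and 9 either way of adjusting. Transposable element genes were 5 higher and 6 lower of 94, or 12 and 11 adjusted over the list alone, with a median of −0.23 against −0.102 to 0.11 in random lists. That median rested on 1 library and was −0.087 without WT_ctrl replicate 1.

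In control medium edgeR called 0 genes in several lists, and the number at an unadjusted p below 0.05 and the number called by DESeq2 follow. They were 1 and 0 for the SMC5/6 complex, 1 and 0 for cohesin and condensin, 3 and 0 for G2/M, 6 and 0 for S phase, 5 and 2 for methylation and silencing, and 1 and 0 for methylation-silenced reporters. The jasmonate list had 4 and 0, pyrimidine metabolism 3 and 0, root markers 0 and 0, and stomatal markers 0 and 0. Adjusted over the list alone 1 silencing gene was higher and 2 were lower, 1 reporter was higher, and the other 8 lists had 0. The random lists do not measure spread between replicates. Medians lay outside them for G2/M at −0.202 (−0.11 to 0.112) and S phase at −0.189 (−0.111 to 0.11). The jasmonate median of 0.57 did as well (−0.181 to 0.22). The reporter QQS stood at 2.03, CMT3 at −0.47, the cyclins CYCB1;3 and CYCA3;1 at −0.47 and −0.73, and LOX3 at 1.41, none past the test. Without WT_ctrl replicate 1, 102 genes were higher and 28 lower, and without nse4a-2_ctrl replicate 2, 114 and 22, with 17 and 15 of 26 rule-named calls passing. Without WT_ctrl replicate 1 the salicylic acid, oxidative, sensing and repair, meristem, clock, housekeeping and histone rises and the heat and leaf marker falls went to 0, the transposable element falls numbered 1, and without WT_ctrl replicate 2 the transposable element rises numbered 2. Without WT_ctrl replicate 2 there were 348 and 52, without nse4a-2_ctrl replicate 1 there were 293 and 66, and without nse4a-2_zeb replicate 1 or 2 there were 380 and 375 higher with 111 lower each time. With DESeq2 and the replicate block the salicylic acid rises numbered 4 and 5, the oxidative rises 5 and 5, the low-oxygen falls 2 and 3, the clock rises 2 and 2, the leaf marker falls 2 and 1, the histone rises 2 and 1 and the transposable element falls 9 and 9. The damage list gave between 5 and 8, and GMI1, NAC044, NAC085, SMR7, PARP2, LTI78, COR15A, COR15B, LTI30, KIN1, ADH1 and SUS1 were called without any 1 library. The authors called 930 genes higher and 332 lower here, and 534 of the 617 edgeR calls were among theirs in the same direction.

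In zebularine the mutant differed from wild type by more genes than in any other comparison, with damage, defence and evening clock genes higher and histone genes lower. The comparison asks how far the treated genotypes stand apart. Of 19682 genes 2541 were higher and 1789 lower in nse4a-2. The same direction in control medium was called for 341 of the higher and 112 of the lower genes, against 58.0 and 15.3 for independent lists, and 7 genes were called in opposite directions. Damage-inducible genes were higher in 17 of 22 cases, with a median of 0.903, and adjusted over the list alone 17 were higher and 2 lower. GMI1 was higher by 2.44 ± 0.17 (adjusted p 3.5e-05), NAC085 by 4.34 ± 0.29 (adjusted p 2.89e-05), SMR7 by 3.02 ± 0.24, NAC044 by 1.83 ± 0.16, CYCB1;1 by 1.24 and the small-RNA effector AGO2 by 1.70. RAD17 was higher by 1.29 ± 0.15 and RAD9 lower by 0.80 ± 0.20, of 19 sensing and repair genes either way of adjusting, with MRE11 at −0.40 and HUS1 at 0.59.

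The 8 largest rises by the naming rule included PNP-A, LTI30 and COR15A. PNP-A was higher by 8.29 ± 0.34 (adjusted p 2.62e-06), AT3G60420 by 5.95 ± 0.28, the phospholipase PLA2A by 5.40 ± 0.38 and ARCK1 by 5.99 ± 0.43. LTI30 was higher by 6.77 ± 0.44, COR15A by 5.45 ± 0.37, COR15B by 5.19 ± 0.39 and the galactinol synthase GolS3 by 6.22 ± 0.49. PBS3 was higher by 6.26 ± 0.37 (adjusted p 1.48e-05), FMO1 by 5.72 ± 0.58, PR2 by 4.36 ± 0.60 and PR1 by 4.30 ± 0.59, among 14 calls of 19 salicylic acid genes, 17 adjusted over the list alone, with a median of 2.05. The oxidative list had 6 of 9 higher either way of adjusting, with UPOX at 1.98 and GSTU24 at 2.48. ELF4 was higher by 4.53 ± 0.47, GI by 2.07 ± 0.32 and TOC1 by 1.99 ± 0.21, and LHY and RVE8 were lower by 0.80 and 1.01. Of 11 clock genes 6 were higher and 2 lower, 7 and 2 adjusted over the list alone, with PRR5 at 1.84 not past it. SUS1 and ADH1 were higher by 2.98 ± 0.14 and 2.84 ± 0.17, and HRA1 and PCO2 lower by 2.94 and 2.73. The low-oxygen list gave 4 higher and 4 lower of 9, 4 and 5 adjusted over the list alone, with a median of −1.33, or −1.63 to −0.678 without 1 library. The jasmonate list was split, with TAT3 and PDF1.2 higher by 4.69 and 2.98 and JAZ7 lower by 3.21, of 14 tested either way of adjusting. HSFA2 and HSP90.1 were higher by 2.09 and 1.39, of 8 heat genes, 3 adjusted over the list alone, with BIP3 at 1.37.

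All 13 histone H3.1 and H4 genes were lower in the mutant in zebularine either way of adjusting, with a median of −1.004, and the H4 gene AT1G07660, uncertain as a near-identical copy, was lowest at −1.81 ± 0.17. CMT3 was lower by 1.05 ± 0.12, RDR2 by 0.86 ± 0.21, AGO4 by 0.68 ± 0.11, CMT2 by 0.61 and VIM1 by 0.53, and DRM1 was higher by 2.93 ± 0.45 and MORC6 by 0.54, of 23 silencing genes either way of adjusting. The reporters SDC and BNS were lower by 2.63 ± 0.75 (adjusted p 0.0332) and 0.49 ± 0.15 (adjusted p 0.0484), and QQS at 1.62 did not pass over all genes and was higher adjusted over the list alone. The 2 reporter calls were 1 with DESeq2, the replicate block or RLE scaling and 0 without WT_zeb replicate 1. SYN3 was lower by 1.18 ± 0.16, CAP-D2 by 0.61 and CAP-H by 0.51, of 13 either way of adjusting. CYCB1;3 and CYCA1;1 were lower by 0.71 and 0.82 among 3 lower G2/M genes of 22, or 2 adjusted over the list alone. The S-phase list had 4 lower, PCNA1 at −0.53 and PCNA2 at −0.50 among them, and 2 higher with TIL1 at 1.10, and 6 and 2 adjusted over the list alone. SOC1 and KNAT6 were higher by 1.46 ± 0.19 and 0.87 ± 0.15, among 2 higher and 1 lower of 19 meristem genes either way of adjusting. PYD3, TK1A and PYD1 were higher by 0.88, 0.62 and 0.60, among 4 higher and 1 lower of 9 pyrimidine genes, 4 and 4 adjusted over the list alone. UBQ10 at 0.92 was alone of 9 housekeeping genes and COBL9 at 4.45 alone of 6 root markers, and FAMA was higher by 0.60 and EPF2 lower by 1.39 of 7 stomatal markers, each either way of adjusting. Of 10 leaf markers edgeR and DESeq2 called 0, adjusted over the list alone 0, and 1 had an unadjusted p below 0.05, with CA1 at 1.18 and CAB1 at 0.20. Transposable element genes were 8 higher and 8 lower of 94, and 8 and 6 adjusted over the list alone.

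The largest falls by the naming rule, which ranks by FPKM, included MRD1 (AT1G53480), with 8 reads against 1846 and lower by 7.57 ± 0.46 (adjusted p 1.61e-05), and AT3G01345, with 8 against 2794. AT2G20670 was lower by 4.59 ± 0.98. The rule also named AT3G47348, AT2G23321, SNOR77, AT3G25011 and AT5G41109, each with 0 reads in nse4a-2_zeb and 2 to 6 in WT_zeb and under the low-count filter. Without nse4a-2_zeb replicate 2, 1251 genes were higher and 524 lower, and 45 of 65 rule-named calls passed, with 0 G2/M falls, 1 low-oxygen fall and 1 pyrimidine rise. Without nse4a-2_zeb replicate 1 there were 1873 and 842, with 0 S-phase falls, and without WT_zeb replicate 1 there were 1646 and 890, with 2 low-oxygen and 4 clock rises, 2 transposable element falls, 1 heat rise, 1 clock fall and 0 calls of SMC5/6, housekeeping and RAD9. Without WT_zeb replicate 2 there were 2033 and 1162, with 2 silencing falls, 1 cohesin and condensin fall and 0 meristem and jasmonate falls. The transposable element rises were 12 without nse4a-2_ctrl replicate 1, and DESeq2 gave 4 transposable element falls, 2 S-phase falls, 3 pyrimidine falls and 0 for RAD9. The damage list gave 15 to 17 and the histone list 12 or 13 over the 8 fits.

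The difference between the genotypes' responses was tested directly, and it called genes of the histone and salicylic acid lists. The test asks which zebularine responses depend on the genotype. In nse4a-2 the response was more positive for 108 genes and more negative for 44. Of the 108, 93 were rises called in nse4a-2 and not in wild type, 9 were falls called in wild type and not in nse4a-2, and 6 were called in both. Of the 44, 31 were falls called in nse4a-2 and not in wild type, 7 rises called in wild type and not in nse4a-2, and 6 both. RCI2A, a small membrane protein of the cold response and chosen after values were seen, fell by 1.94 in wild type and rose by 0.63 in nse4a-2, a difference of 2.57 ± 0.16 (adjusted p 0.000725). EDS5 differed by 2.80 ± 0.37 (adjusted p 0.0207), with 0.28 in wild type and 3.08 in the mutant. ICS1 differed by 1.87 ± 0.23 (adjusted p 0.0180) and EDS1 by 1.65 ± 0.30 (adjusted p 0.0453), and they were the 3 calls of 19 salicylic acid genes, 8 adjusted over the list alone, with a list median of 1.11, or 0.723 to 1.704 without 1 library. FMO1 at 5.01 (adjusted p 0.0671), PAD3 at 2.99 and PBS3 at 4.11 did not pass. SUS1 differed by 1.45 ± 0.20 (adjusted p 0.0207), alone of 9 low-oxygen genes, or 2 adjusted over the list alone. AGO2 differed by 1.35 ± 0.21 (adjusted p 0.0266), alone of 22 damage-inducible genes, or 2 adjusted over the list alone, with CYCB1;1 at 0.80 and XRI1 at 0.88 not past it. The damage genes GMI1, SMR7, NAC044 and NAC085, called in both genotypes, were not called here, and NAC085 stood at −0.70 ± 0.67.

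Histone genes differed the other way. The H3.1 gene AT3G27360 differed by −1.53 ± 0.24 and the H4 genes AT3G45930, AT3G46320, AT3G53730 and AT5G59970 by −1.20, −1.13, −1.18 and −1.03, all uncertain singly as near-identical copies. They were 5 calls of 13, 12 adjusted over the list alone, with a list median of −0.946 against −0.215 to 0.122. COL2, RPT2 and UNE10, chosen after values were seen, differed by −2.51 ± 0.26, −1.505 ± 0.18 and −2.17 ± 0.29. COL2, a B-box gene related to CONSTANS, rose by 1.72 in wild type and fell by 0.80 in the mutant. PRR7 differed by 1.15 ± 0.19 (adjusted p 0.0352), alone of 11 clock genes, where 6 differed upward and 1 downward adjusted over the list alone, with ELF4 at 2.96 (adjusted p 0.0581), GI at 2.06 and TOC1 at 1.36. COBL9 differed by 5.76 ± 0.99 (adjusted p 0.0362), alone of 6 root markers either way of adjusting, on 16 and 5 reads in wild type against 6 and 99 in the mutant. Of 94 transposable element genes AT4G16870 differed by 1.79 and AT3G28160 by −1.67, either way of adjusting. The largest differences by the naming rule, PNP-A at 4.90 ± 1.64 and AT1G58684 at −11.79, did not pass (adjusted p 0.211 and 0.264), and the rule's other genes, AT1G02490, AT2G05765, AT1G74456, AT3G12835, AT3G47348, SNOR77, AT2G23321 and AT3G04854, were under the low-count filter.

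The remaining lists had 0 calls by edgeR for the difference, and the numbers at an unadjusted p below 0.05 and by DESeq2 follow. They were 1 and 0 for SMC5/6, 2 and 0 for cohesin and condensin, 1 and 0 for sensing and repair, 0 and 0 for G2/M, 3 and 1 for S phase, 3 and 0 for silencing, 1 and 0 for reporters and 3 and 1 for meristem genes. Jasmonate had 8 and 2, heat 4 and 2, oxidative genes 5 and 1, pyrimidine 1 and 0, housekeeping 0 and 0, leaf markers 1 and 1, and stomatal markers 2 and 1. Adjusted over the list alone 4 oxidative genes, 3 heat, 2 jasmonate and 1 each of SMC5/6, meristem, leaf and stomatal genes differed upward, and 2 meristem and 1 each of reporter, jasmonate, heat and stomatal genes downward. Among them HSFA2 stood at 4.02, PDF1.2 at 2.51, NAC013 at 1.02, SOC1 at 1.25, TAT3 at 6.40 and JAZ8 at −2.75. The self-test recovered 42.7% of 2-fold differences of response and 93.9% of 4-fold ones, so moderate differences may often have been missed. Its data were simpler than the real libraries. Counts moved with every library: 16 and 3 genes without WT_ctrl replicate 1, 20 and 16 without WT_ctrl replicate 2, 6 and 1 without nse4a-2_ctrl replicate 1, and 54 and 24 without nse4a-2_ctrl replicate 2. They were 75 and 26 without WT_zeb replicate 1, 185 and 45 without WT_zeb replicate 2, 56 and 14 without nse4a-2_zeb replicate 1, and 5 and 0 without nse4a-2_zeb replicate 2. The 5 histone calls went to 0 without WT_ctrl replicate 1 and the 3 salicylic acid calls to 0 without nse4a-2_ctrl replicate 1, while DESeq2 gave 11 and 8 and the replicate block 8 and 8. Clock rises numbered 3 with DESeq2, 4 with the replicate block and 0 without WT_ctrl replicate 1, and the transposable element rise went to 0 with RLE scaling. ICS1 was called in 6 of the 8 fits, EDS5 and SUS1 in 5, and PRR7 and COBL9 in 0.

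**Figure D3:**
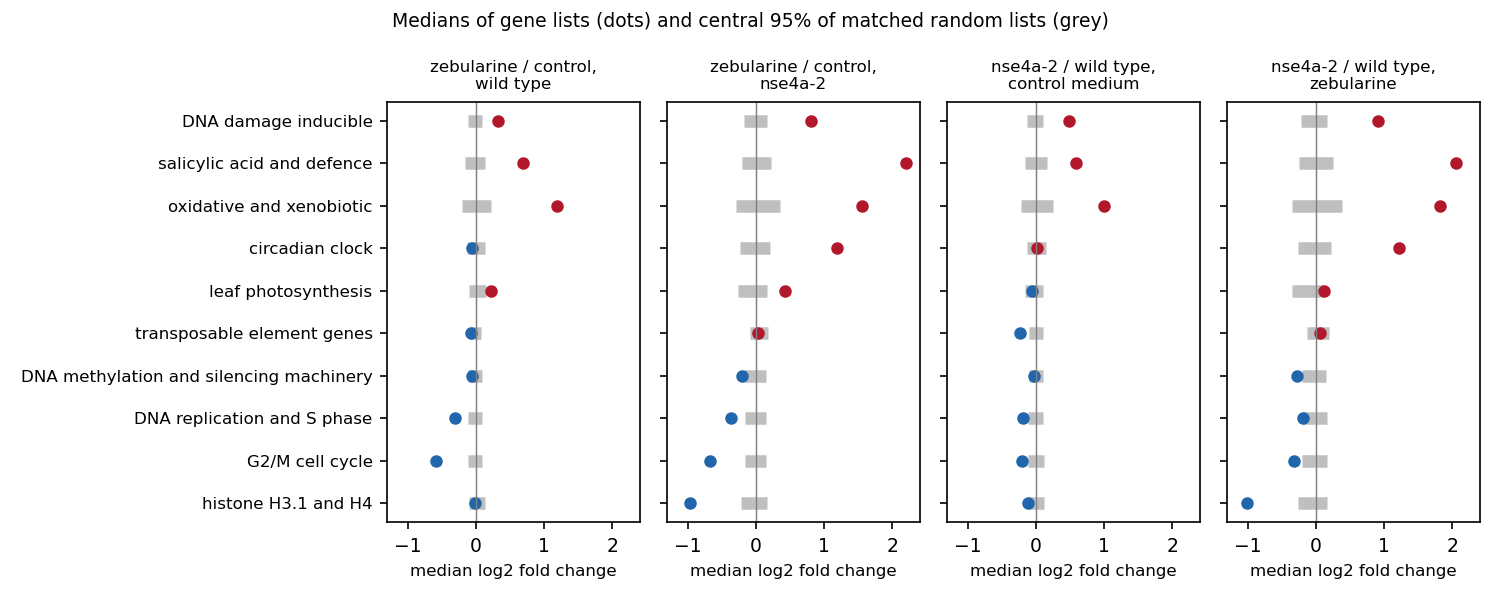
Dots give the median log2 fold change of 10 gene lists in the 4 comparisons of 2 groups, and grey bars the central 95% of matched random lists. The salicylic acid list reaches 2.19 and the histone list −0.961 for zebularine in nse4a-2, against 0.689 and −0.015 in wild type.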

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

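The tests of the histone pattern below were chosen after the result was seen. The zebularine response differed between genotypes, by edgeR's quasi-likelihood test of the difference itself, for 108 genes in the positive and 44 in the negative direction. Among the genes named by rule or list, EDS5 in salicylic acid synthesis differed by 2.80, SUS1 by 1.45, AGO2 by 1.35 and the root-hair gene COBL9 by 5.76. The H3.1 gene AT3G27360 differed by −1.53 and the H4 genes AT3G45930, AT3G46320 and AT3G53730 by −1.20, −1.13 and −1.18. The counts fell to 5 and 0 without nse4a-2_zeb replicate 2 and to 6 and 1 without nse4a-2_ctrl replicate 1, and they were 16 and 3 without WT_ctrl replicate 1, 20 and 16 without WT_ctrl replicate 2, 54 and 24 without nse4a-2_ctrl replicate 2, 75 and 26 without WT_zeb replicate 1, 185 higher without WT_zeb replicate 2, and 56 and 14 without nse4a-2_zeb replicate 1.

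The histone genes fell with zebularine in nse4a-2 and not detectably in wild type, and the difference was called for 5 of 13. Reads moving between near-identical copies would leave their sum in place, but the summed CPM of the 13 genes changed by −0.91 log2 in nse4a-2, against 0.02 in wild type. The S-phase list did not share the difference, with a median of 0.004 and an SD of 0.31 across its members, against −0.946 for the histone list. That would argue against a lower share of cells in S phase only if those genes follow S phase as closely as histone genes do. This was not tested, so a lower share stays open. Another candidate explanation that stays open is a change in histone transcripts themselves, such as their stability or their capture by poly(A) selection, which these libraries do not separate. The 5 calls went to 0 without WT_ctrl replicate 1, and were 11 with DESeq2 and 8 with the replicate block.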

How the results depend on the processing

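The edgeR and DESeq2 settings here, and leaving libraries out for medians, named and shared genes, were chosen after the data were seen, while the size-rule and authors' threshold settings, and leaving libraries out for counts of changed genes, were planned. Counts are higher, then lower, in the order wild type with zebularine, nse4a-2 with zebularine, genotype in control medium, genotype in zebularine, and difference. RLE scaling kept every total of called genes within 1.5 times and moved list medians by at most 0.012, and no rule-named call reversed under RLE, DESeq2 or the block. At an adjusted p below 0.01 edgeR called 53 and 12, 760 and 295, 117 and 23, 1428 and 577, and 3 and 0. Without the low-count filter it called 851 and 276 for wild type, 965 and 332 for the genotype in control medium and 363 and 214 for the difference, with the replicate block 749 and 206, 845 and 314, and 288 and 168, and with DESeq2 677 and 219, 726 and 262, and 333 and 163. A fit of the 2 groups alone gave 150 and 48 for wild type, with fewer libraries to estimate the spread. Leaving out 1 library, with the lone sample assumed to vary like the other groups, gave 18 to 447 and 5 to 124, 552 to 1902 and 161 to 1171, 102 to 576 and 22 to 247, 1251 to 2757 and 524 to 2081, and 5 to 185 and 0 to 45. By the size rule, a pseudocount of 0.1 gave 730 and 202 for wild type, 340 lower for nse4a-2, 815 and 262 for control medium, 546 lower in zebularine and 550 lower for the difference. A pseudocount of 5 gave 203 and 57, 433 and 48, 177 and 64, 598 and 98, and 318 and 133. A mean FPKM of at least 5 gave 81 lower for wild type, 520 and 108 for nse4a-2, 97 lower in control medium, 702 higher in zebularine, and 343 and 214 for the difference. A 1.5-fold size gave 1129 and 444, 1822 and 1012, 1337 and 565, 2202 and 1276, and 1564 and 1140, and a 4-fold size 52 and 25, 198 and 25, 51 and 43, 304 and 36, and 134 and 39. The authors' adjusted p below 0.01 gave 542 and 135 for wild type, 358 lower for nse4a-2, and 573 and 164 for control medium, and their calls at 2-fold 386 and 66, 760 and 111, and 375 and 89. Genes shared by both zebularine responses numbered 183 and 21 by the size rule and 156 and 51 by edgeR, against 410 and 92 by the authors' calls. Of 45 list medians, a pseudocount of 5 moved 24 past the replicate SD and reversed 1, no filter moved 14, centring and the authors' group means 13 each, a mean FPKM of at least 5 moved 11, a pseudocount of 0.1 moved 5, and leaving out 1 library 0 to 8 with 0 or 1 reversed. The low-oxygen median of nse4a-2 with zebularine, −0.435, was 0.028 at a pseudocount of 5, and leaving out 1 library it ran from −0.964 to 0.381, that of wild type from −0.663 to 0.034, and the jasmonate median between genotypes in zebularine from −0.588 to 0.127. Except for thresholds, filters and group numbers, which act by construction, the cause was not tested. Leaving out libraries was not run for the size rule and the authors' calls, which rest on 2-replicate means, and the fit of 2 groups does not apply to the difference.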

Other observations

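The genes, the family tests and the tests of explanations in this part were chosen after the results were seen, while the edgeR contrasts were planned. Of 8 gene families, tested for calls by Fisher's exact test, one-sided, with Benjamini-Hochberg adjustment over 80 tests, 6 rose more often than other genes with zebularine in nse4a-2. Members of a family are not independent. Cysteine-rich receptor-like kinases rose with zebularine in nse4a-2 for 18 of 32 members (56.2%, against 8.9% of other genes, adjusted p 6.84e-10), and 3 were called for the difference of responses (adjusted p 0.00315). TIR-NBS immune receptors rose for 22 of 70 (adjusted p 1.27e-06), WRKY transcription factors for 17 of 54 (adjusted p 2.34e-05), NAC transcription factors for 16 of 52 (adjusted p 4.42e-05) and receptor-like proteins for 15 of 42 (adjusted p 1.69e-05), with 5 receptor-like proteins called for the difference (adjusted p 2.39e-05). Light-harvesting and photosystem genes rose with zebularine for 6 of 50 in wild type (adjusted p 0.00092) and 18 in nse4a-2 (adjusted p 1.56e-06), and 8 were lower in the mutant in control medium (adjusted p 1.51e-07). B-box genes rose in wild type for 5 of 17 (adjusted p 4.3e-05), and in control medium 4 were higher and 3 lower in the mutant (adjusted p 0.00236 and 0.0019). NAC genes also rose in wild type for 4 of 52 (adjusted p 0.0412), and 5 were higher in the mutant in control medium (adjusted p 0.026). Ribosomal protein genes were lower in nse4a-2 in zebularine for 102 of 290 (35.2%, against 8.7%, adjusted p 3.71e-33), while zebularine in nse4a-2 lowered 17 (5.9%, against 5.7%, adjusted p 1.0). With zebularine in wild type, between genotypes in control medium and for the difference of responses, 0 of 290 were called in either direction.

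Several genes were read in wild type and nearly or wholly unread in nse4a-2 in both media. With a single mutant line, an effect of the lesion on them cannot be told apart from another difference between the lines. In the order WT_ctrl, nse4a-2_ctrl, WT_zeb and nse4a-2_zeb, MRD1 (AT1G53480) had 1742, 1, 1846 and 8 reads, AT3G01345 had 1112, 6, 2794 and 8, and the histone deacetylase gene hda17 (AT3G44490) had 59, 2, 21 and 0. The LINE element gene AT2G01550 had 107, 0, 97 and 0 reads, at least 33.2-fold and 27.7-fold lower. AT3G28320 departed from this, with 364, 0, 109 and 14, lower in nse4a-2 in zebularine but not nearly unread there as a group. Those 14 reads, 0.403 ± 0.570 CPM, all came from a single library. In the opposite direction AT5G60250 had 59, 960, 375 and 1928. Of the 94 transposable element genes tested, 23 were called in at least 1 comparison.

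LTI78, COR15A and LTI30, known from the cold response and picked here for their large changes, were higher in the mutant in both media. LTI78 stood at 30.7, 377, 83.8 and 1900.0 CPM in the same order, COR15A at 1.77, 22.3, 2.997 and 131, and LTI30 at 1.47, 19.3, 2.31 and 249.9. With zebularine in nse4a-2 they rose by 2.34, 2.56 and 3.70. The difference of their responses from those of wild type did not pass, at 0.90, 1.85 and 3.06 (adjusted p 0.533, 0.172 and 0.0786, edgeR's quasi-likelihood test).

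AT1G51120, an AP2/B3 transcription factor gene next to NSE4A in locus order, had 0 and 1 reads in wild type in control medium and zebularine, and 77 and 105 in nse4a-2. Induction by DNA damage in proportion to GMI1 is argued against, since wild type in zebularine would then have had 52.3 reads and had 1. In nse4a-2 the gene changed by 0.40 ± 0.38 with zebularine, not past the test, while GMI1 rose. Induction by damage in another proportion was not tested. A changed transcript at the neighbouring NSE4A locus may be the source, and the gene stood between 2.30 and 3.44 CPM in each of the 4 mutant libraries. That cannot be told apart from an effect of the mutation on the gene itself, since the lesion is not given and counts per gene show no transcript ends.

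The morning clock genes CCA1, LHY and RVE8 rose with zebularine in both genotypes, and the evening genes ELF4 and TOC1 fell in wild type. A shared shift would be harvest of both zebularine groups at the same hour and of both control groups at another. As the only cause for the evening genes TOC1, GI, ELF4 and LUX it is argued against. Their median was 0.38 in nse4a-2, each of them above all 4 in wild type. However, edgeR's test of the difference of responses called none of these 4, and PRR7 was its only call of 11 clock genes. A shared shift together with an effect of genotype was not covered and stays open. For the morning rise and for other clock-controlled genes that shared shift of hour stays open, with JMJD5 at −0.94 and GRP7 at −0.99 in nse4a-2, lower as in wild type, and PRR3 at 0.09 and COR27 at 0.46. There it cannot be told apart from an effect of zebularine, since harvest hours are not given. Harvest of wild type alone at another hour does not account for the morning rise, since CCA1, LHY and RVE8 had a median of 1.83 in nse4a-2 as well, against 2.49 in wild type. For the evening genes of wild type, with a median of −0.97, another harvest hour cannot be told apart from an effect of zebularine, since harvest hours are not given. Harvest of each of the 4 groups at its own hour was not covered by these comparisons and stays open.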
